A study of Drosophila melanogaster with 4 samples.

How the data were processed

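The series measured the distribution of H3K79me1, monomethylation of histone H3 on a lysine in its globular core, by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from the heads of adult Drosophila melanogaster. The flies were wild-type Oregon-R adults, labelled as a mixed adult stage, and heads were separated from whole flies by sieving. Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, chromatin was released with SDS and sonication, and the antibody came from lot 1 of a commercial supplier. There were 4 samples, 2 ChIP libraries and 2 input libraries of genomic DNA. Each input is tied by its label to the region list of the ChIP library with the same replicate number. The labels do not say whether the replicates came from separate collections of flies, so spreads between them may be technical.

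Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited 1 list of enriched regions for each ChIP replicate and 1 list for the combined replicates, 3 region lists in all. The coordinates are on FlyBase release 5, per the file headers, which also give the lengths of 14 sequences. The region caller, its threshold, its minimum width, any read filter and the way in which the replicates were combined are not given in the sources used here. The inputs have no region list or signal of their own and enter only through the authors' calls. The depth of each library is unknown from these files, so no value has an interval that needs it. The intervals given for shares of regions are 95% Wilson intervals, which treat regions as independent draws and cover counting error only.

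The value that the authors deposited with each region is a score without a stated unit, treated here as a log2 value. The scale was read from the values. Within each list, the base of each candidate scale was raised to the difference between a region's score and the most frequent score, and the result was compared with ratios of whole numbers, with denominators up to 5000 and a relative tolerance of 1e-11. On the log2 scale 99.3% of replicate 1 regions, 99.9% of replicate 2 regions and 96.9% of combined regions gave such a ratio. On the natural log and log10 scales the shares lay between 0.518% and 1.18%. The constant that scales the ratio is unknown, so scores serve only to describe, rank or filter regions within a list, and differences between scores are differences in log2. The combined list holds 1 region that the authors named as depleted, which was left out of every count of enriched regions.

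Header lines that had been joined to one another were split before parsing. Coordinates are 1-based. Widths, covered lengths and covered shares were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A region counted as shared where at least 1 bp lay inside a region of the other list. Base-pair overlap was expressed as the Jaccard index, the length inside both lists over the length inside either. Chance overlap was taken from 1000 circular shifts of the replicate 1 list (or of the replicate 2 list, for its own share) within each sequence, which keep widths and spacing, in a one-sided permutation test whose smallest possible p is 0.000999. Chance shares of single classes of regions came from 1000 further shifts, counted after the data had been seen. Random placement used 100 draws of bedtools 2.31.1 shuffle within each sequence. Score ranks were compared by Spearman's rho over overlapping pairs of regions, without a p-value because regions are not independent replicates. Covered shares were also taken in 1189 windows of 100 kb on the 5 large arms, and in 10 equal bins along each of these arms counted from the telomere. The X was compared with the 4 large autosomal arms by exact permutation over the 5 arms, one-sided, for which 0.2 is the smallest possible p.

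The methods were tested on simulated lists on the same sequences. A list of 5000 regions was compared with a second list that held a random 70% of them at the same coordinates. The recovered share of 70.0% and Jaccard index of 0.705 equalled the planted values. The copying fixes both, so they check only the computation, without shifted boundaries or regions private to the second list. Spearman's rho over 3500 simulated pairs was 0.704 for a planted 0.690. Of 40 pairs of independent simulated lists of 2000 regions, 1 gave p under 0.05 in the shift test. These lists were placed at random, with fewer regions and fewer shifts than in the data, so clustered regions were not covered by this check.

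The groups, tests and most alternatives were fixed before the data were examined. The alternatives were a minimum overlap of 50% of one or both regions, the higher-scoring 50% of regions, equal numbers of top-scoring regions, merging of regions within 1000 bp, a minimum width of 1000 bp, random placement, other rules for pairs, each replicate list alone, and bases inside both lists. The named regions were chosen by a rule set beforehand, namely the 5 highest-scoring and 5 widest of each list and the 5 widest of each replicate list without a base in the other. Region-free stretches of at least 100 kb and regions of at least 10 kb were examined after the data had been seen.

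Results that need gene models were not run. The gene table at hand belongs to a release 6 assembly, and coordinates of different releases cannot be mixed, so the planned comparisons of gene features, positions along genes, marked genes and gene lists are not analysed here and regions are named by position alone.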

Results

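H3K79me1 was mapped in head nuclei of wild-type adult flies with 2 ChIP libraries and 2 input libraries. Methylation at this position of histone H3 is deposited by enzymes of the Dot1 family, represented in flies by the product of the gene grappa, and is generally found over transcribed genes. The measurements are the authors' lists of regions in which the ChIP signal exceeded the input. Each region has a position on FlyBase release 5 and the authors' own score. That score has no stated unit and is treated here as log2. Library depth is unknown. The comparisons below concern how much of the genome lay in such regions, how far the replicates marked the same sequence, and how the regions were spread over the chromosomes.

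H3K79me1 regions covered 22.4 Mb in replicate 1 and 23.9 Mb in replicate 2, or 18.1% and 19.5% of the 6 chromosome arms (mean 18.8% ± 0.961, SD, n = 2). Replicate 1 held 7603 regions and replicate 2 held 8137 (mean 7870 ± 378, SD, n = 2). The combined list was larger, with 12942 regions over 42.9 Mb, or 35.0% of the arms. That length was 1.85 times the mean of the replicate lists, a gap far wider than the spread between the replicates. Median widths were close to 2 kb in all 3 lists, at 2051 bp, 2053 bp and 2001 bp, and the mean widths were 2942 bp, 2939 bp and 3311 bp. The narrowest region was 1301 bp in both replicate lists and 1001 bp in the combined list. Wider regions scored higher within each list, with Spearman's rho between width and score of 0.64 in replicate 1, 0.61 in replicate 2 and 0.49 in the combined list, across regions that are not independent replicates.

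The widest region of the combined list spanned 90045 bp on 3R from 21169274 to 21259318, with a log2 score of 0.90. Replicate 1 covered 94.3% of it with 6 regions and replicate 2 covered 91.6% with 4. The widest replicate 2 region, 69.1 kb on 3R from 21183117 to 21252229, lay inside this domain. Next in the combined list came 72.6 kb on 2R from 2389970 to 2462572, of which the replicates covered 86.2% and 86.5%. A domain of 61.7 kb on 3R from 15760668 to 15822356 was covered to 92.1% by replicate 1 and 76.7% by replicate 2. On 3L, 59.2 kb from 15722754 to 15781986 were covered to 51.9% and 75.4%. On 2L, 55.9 kb from 14521670 to 14577580 were covered to 77.5% and 86.8%. The widest replicate 1 region lay on 3L from 9627935 to 9663654 (35.7 kb, log2 score 1.06), entirely within a replicate 2 region of 41.1 kb. A second wide domain was nearly identical in the replicates, on 2R from 580287 to 615573 in replicate 1 and from 581513 to 614992 in replicate 2.

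The highest-scoring regions of the combined list were narrow and had no counterpart in the replicates. The 5 highest were 1001 to 1005 bp wide and had no base in either replicate list. Neither replicate list held any region narrower than 1301 bp, so this absence does not show that the enrichment failed to replicate. They were on X from 4683542 to 4684546 (log2 score 3.30), on 3LHet from 2527988 to 2528988, on the unplaced sequence U from 9169928 to 9170928 and on X from 4820218 to 4821218 (3.15 each), and on 2RHet from 1014110 to 1015110 (2.98). The read counts behind these scores are not given, so high scores in such narrow regions may rest on few reads. The top region of replicate 1, on 2RHet from 1313025 to 1314794 (log2 score 2.40), had no base in replicate 2. The top region of replicate 2, on U from 5623985 to 5625287 (2.18), had none in replicate 1. Among the 5 highest-scoring regions of each replicate list, overlapping ones were found on 2R, from 303732 to 305863 in replicate 1 and from 302851 to 307146 in replicate 2, and on X, from 16286224 to 16293820 and from 16285600 to 16294331.

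Most of the length of each replicate list also lay in the other list. Of the replicate 1 regions, 5586 of 7603 (73.5%) had a base in a replicate 2 region, and 5563 of 8137 replicate 2 regions (68.4%) had a base in a replicate 1 region. In total 15.6 Mb lay inside regions of both lists, or 69.6% of the replicate 1 length and 65.1% of the replicate 2 length. A further 6.81 Mb lay in replicate 1 only and 8.36 Mb in replicate 2 only. Shifted lists shared far less. The mean share was 33.6% over 1000 shifts of replicate 1 (highest 36.2%) and 31.6% over those of replicate 2 (highest 34.6%). The Jaccard index was 0.506 against a shifted mean of 0.109 (highest 0.123), a 4.66-fold excess. In each case the one-sided permutation p was 0.000999, the smallest that 1000 shifts can give.

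The share of regions found in the other list differed between classes of width, score and chromosome, and so did the share that chance gives. Of the regions of at least 5 kb, 830 of 832 in replicate 1 and 890 of 894 in replicate 2 were shared (99.8% and 99.6%, against 49.8% and 47.0% in shifted lists). Under 2 kb the shares were 53.9% (95% Wilson interval 52.3 to 55.6) and 46.9% (45.3 to 48.5), against 28.6% and 26.8% in shifted lists. From the lowest-scoring to the highest-scoring of 4 equal classes, the shared part rose from 60.3% to 89.0% in replicate 1 and from 53.8% to 84.8% in replicate 2, while the shifted shares moved from 31.1% to 37.9% and from 28.8% to 34.9%. Width and score were correlated, and their parts were not separated. On the X, 57.0% of replicate 1 regions (53.9 to 60.1) and 62.8% of replicate 2 regions (59.6 to 65.9) were shared. On the 4 large autosomal arms, replicate 1 shares lay between 74.0% on 2L and 78.8% on 2R, and replicate 2 shares between 66.5% on 3R and 70.6% on 3L. As a ratio to shifted lists, the X had a 3.33-fold and 3.36-fold excess and the autosomal arms 1.88-fold to 2.38-fold (replicate 1) and 1.82-fold to 2.37-fold (replicate 2). As a difference, the X lay 39.9 and 44.1 percentage points above shifted lists, within the autosomal range of 36.8 to 42.9 in replicate 1 and above that of 31.3 to 39.4 in replicate 2. The fourth chromosome, the smallest, had the highest share among the 6 arms. It was 56 of 68 regions (82.4%, 71.6 to 89.6) in replicate 1 and 62 of 68 (91.2%, 82.1 to 95.9) in replicate 2. The replicate 1 interval overlapped those of all 4 large autosomal arms. The fourth chromosome's mean share in shifted lists was 35.6% and 36.5%, so its excess as a ratio was below that of the X. Single shifts reached 86.8% and 92.6%. Shifts had no minimum distance, so on so short a sequence some may have left the list nearly in place. These highest values therefore do not measure what chance alone can give. The widest regions without a counterpart were 7.02 kb on X from 14782748 to 14789771 in replicate 1 and 7.78 kb on 3L from 15730199 to 15737980 in replicate 2. The remaining regions named by the same rule were 4.49 to 5.09 kb wide in replicate 1, on X, 3L and 3R, and 4.82 to 7.38 kb wide in replicate 2, on 2R and 3R.

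**Figure D1:**
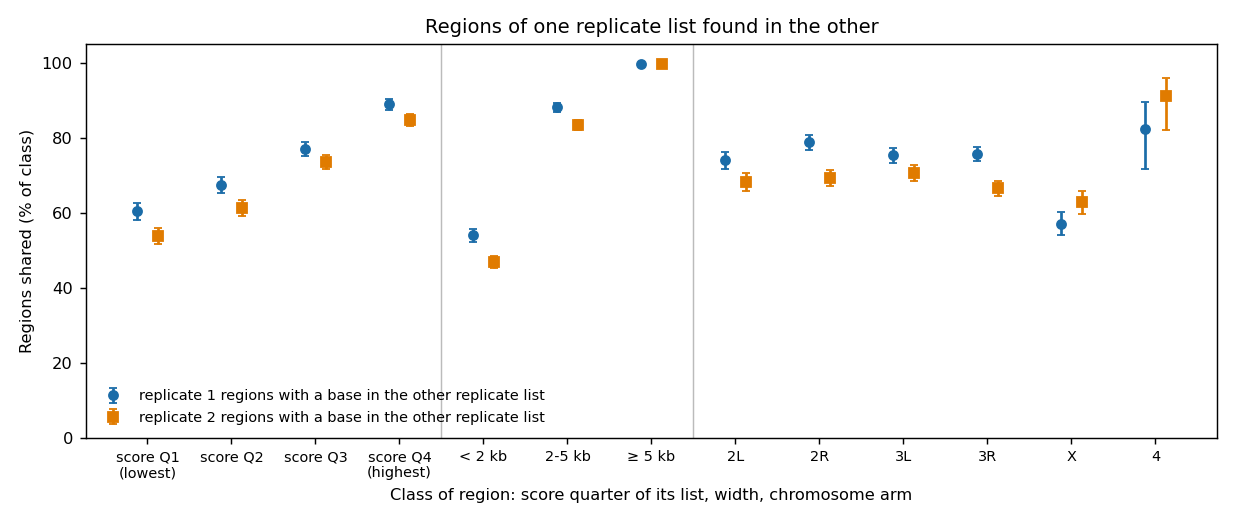
Share of regions of one replicate list (y axis, percent of the class) that have at least 1 base in the other list, by score class (Q1 to Q4), width and chromosome arm (x axis). Circles stand for replicate 1 and squares for replicate 2, with 95% Wilson intervals; the shares reach 99.8% and 99.6% at 5 kb or more and are lowest under 2 kb.

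At the scale of 100 kb the replicates followed each other closely. Across 1189 windows on the large arms, which are not independent, the covered shares of the replicates had a Spearman's rho of 0.93 and a Pearson's r of 0.94. In 64 windows (5.38%) neither replicate held a region. Over 6452 overlapping pairs of regions, in which a region can belong to several pairs, Spearman's rho was 0.49 between the scores and 0.40 between the widths. Where each region covered at least 50% of the other (3757 pairs), it was 0.67 for scores and 0.82 for widths. That rule limits how far the widths of a pair can differ, so the higher rho for widths is partly built in. As width and score were correlated, the rho for scores may be raised too. Over 3607 pairs in which neither region overlapped another, rho was 0.59 for scores and 0.62 for widths.

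**Figure D2:**
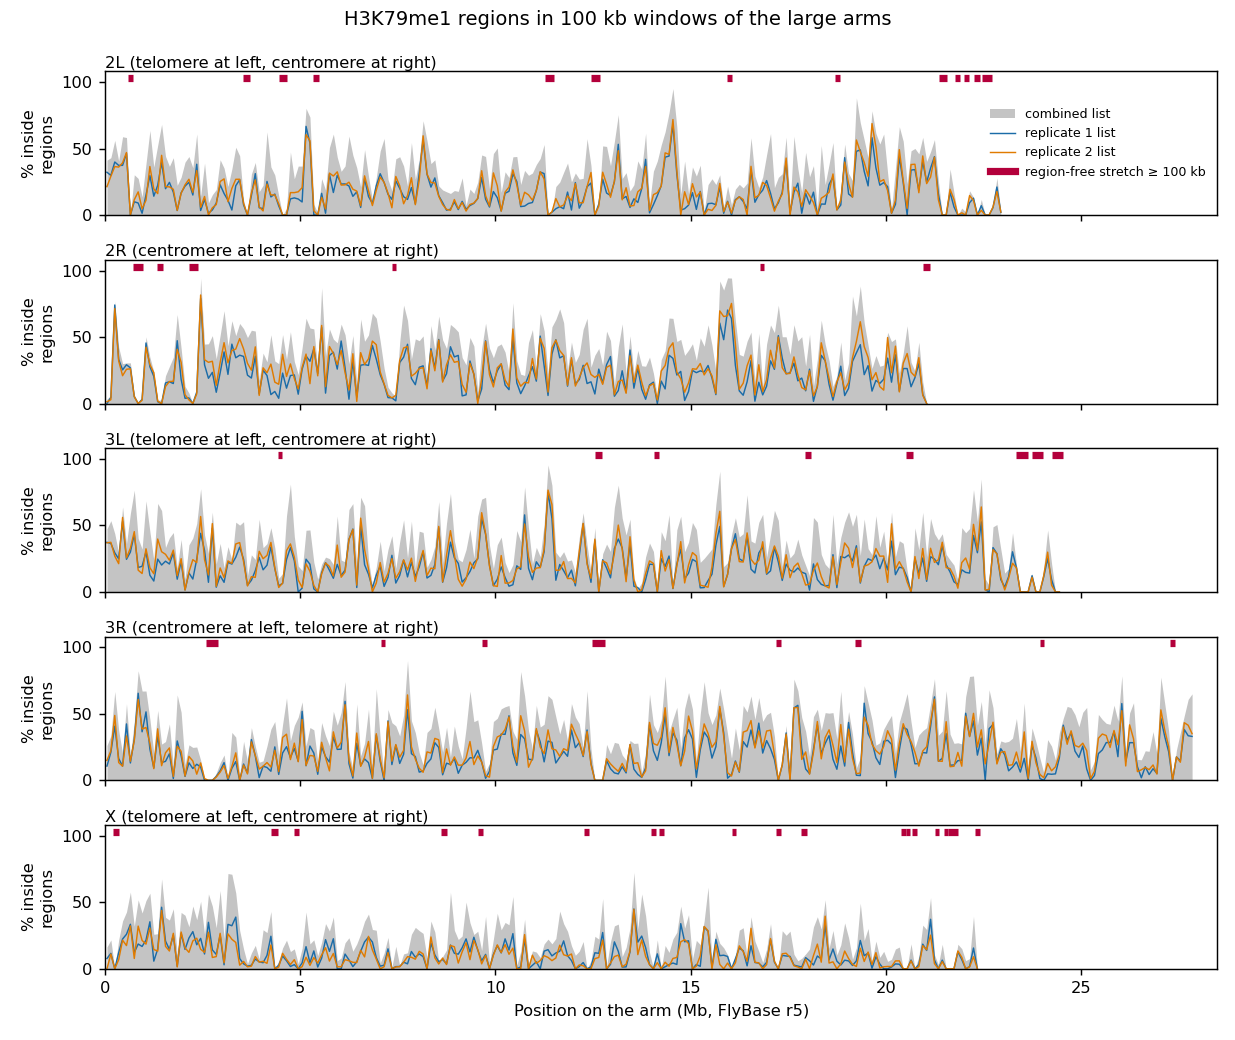
Percent of each 100 kb window inside regions (y axis) along the 5 large arms in Mb (x axis, FlyBase release 5), for the combined list (grey area), replicate 1 (blue line) and replicate 2 (orange line). Bars along the top mark the 53 stretches of at least 100 kb without a combined region; the replicate lines run together over most of each arm (Spearman's rho 0.93).

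The combined list took in nearly all of the replicates' regions and added others. It overlapped 7551 of 7603 replicate 1 regions (99.3%) and 8058 of 8137 replicate 2 regions, leaving out 52 and 79. Of its 12942 regions, 4316 (33.3%) had a base in both replicate lists, 1588 (12.3%) in replicate 1 only, 2057 (15.9%) in replicate 2 only and 4981 (38.5%) in neither. The regions in both were wide, with a median of 4588 bp, and made up 27.1 Mb. Those in neither had a median width of 1321 bp and made up 7.37 Mb. Of these, 2395 (48.1%) were narrower than 1301 bp, the width of the narrowest replicate region. Median log2 scores within the combined list were 0.57 for regions in both replicates, 0.42 and 0.43 for regions in replicate 1 only and in replicate 2 only, and 0.42 for regions in neither.

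H3K79me1 regions covered less of the X than of any large autosomal arm in all 3 lists. The X was covered to 10.0% ± 0.839 (SD, n = 2), against 17.6% ± 0.937 for 2L, 20.2% ± 1.21 for 3L, 21.5% ± 1.61 for 3R and 24.2% ± 2.02 for 2R. In the combined list the X share was 23.7%, below the 33.7% of 2L, 37.0% of 3L, 38.4% of 3R and 41.9% of 2R. Relative to the mean of the 4 autosomal arms, X coverage was 0.534 in replicate 1, 0.430 in replicate 2 and 0.628 in the combined list. The X regions that were listed scored higher. Their median log2 score was 0.76 in both replicate lists, against autosomal means of 0.67 and 0.61, and 0.53 against 0.44 in the combined list. The X lay outside the range of the autosomal arms in each case, and the exact one-sided p over 5 arms was 0.2, the smallest possible.

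The fourth chromosome carried few but wide regions. It held 50.3 regions per Mb in each replicate list, fewer than the autosomal means of 66.7 and 73.3, with median widths of 4293 bp and 2736 bp. Its covered share was 20.4% ± 3.13 (SD, n = 2). Against the autosomal mean it stood above in replicate 1 (22.6% and 19.8%) and below in replicate 2 (18.2% and 21.9%) and in the combined list (28.4% and 37.7%), so its direction depends on the list.

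Sequences assembled from heterochromatin had low coverage but were not empty. The 6 sequences with the suffix Het were covered to 5.89% in replicate 1, 4.93% in replicate 2 and 7.99% in the combined list, by 110, 102 and 154 regions. Coverage was 7.04% ± 0.932 on 2RHet and 7.46% ± 0.564 on 3LHet, and 2.68% ± 0.608 on 3RHet (SD, n = 2). YHet and the unplaced sequence Uextra held no region in any list, and U was covered to 0.166% and 0.156%. All shares are over the full sequence lengths. Assembly gaps and sequence to which reads cannot be assigned were not analysed and would also lower them. All 4 large autosomal arms had a larger covered share in replicate 2, while the X, the fourth chromosome, U and the 5 Het sequences with any region had a larger share in replicate 1. Some of these hold very few regions, with 1 and 2 on 2LHet, 2 and 2 on XHet and 7 and 6 on U in replicates 1 and 2. By regions per Mb, 2LHet (2.71 and 5.42) and 3LHet (17.2 and 18.8) were higher in replicate 2, and the fourth chromosome and XHet were equal.

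**Figure D3:**
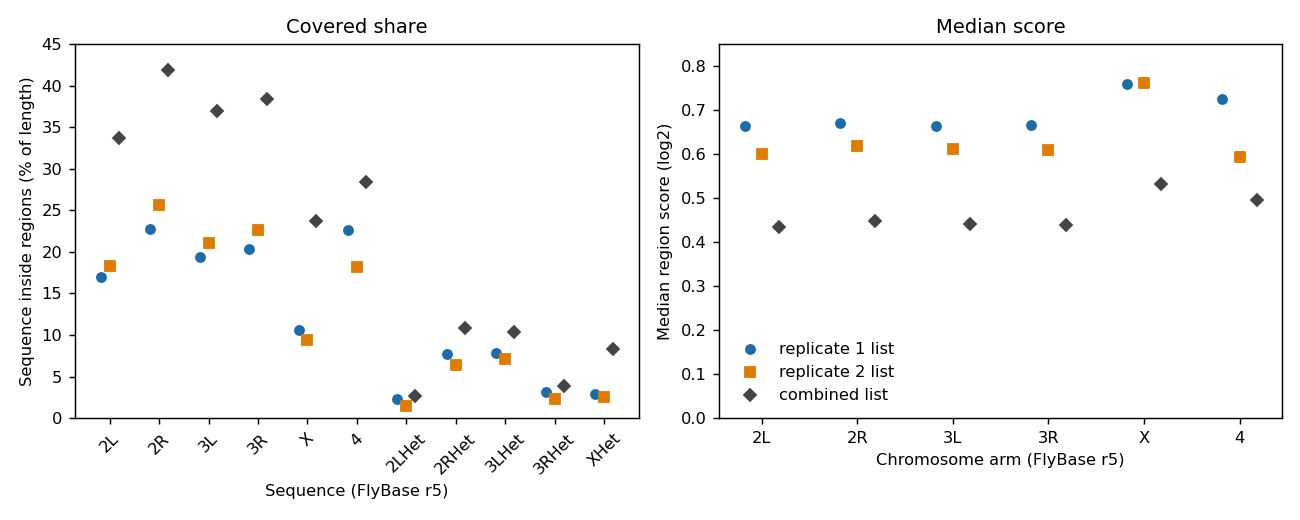
Left, percent of each sequence inside H3K79me1 regions (y axis) for the arms and heterochromatic sequences (x axis); right, median log2 score of the regions on each arm. Circles, squares and diamonds stand for replicate 1, replicate 2 and the combined list; the X has the lowest covered share among the 6 arms (23.7% in the combined list) and the highest median score (0.53).

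Along most arms, coverage was low in the part next to the centromere. Gaps and sequence to which reads cannot be assigned were not analysed and could also lower coverage there. Of 10 equal bins, the centromeric one was the lowest on 2L, 3L and X in all 3 lists and on 2R in replicate 2 and the combined list. In the combined list it was covered to 20.0% on 2L, 26.0% on 2R and 13.6% on X, against means of 35.2%, 43.6% and 24.8% over the other bins of the same arm. On 3L the centromeric bin stood at 0.653 of the mean of the other bins, 38.3%. The drop was limited to that bin on 2L, where the neighbouring bin was the highest of the arm in all 3 lists (44.7% in the combined list). 3R departed from this, with 34.8% in the centromeric bin and its lowest value, 29.0%, in the next. The telomeric bin was the highest of the arm in all 3 lists on the X (19.2%, 17.8% and 36.6%) and on 3L (24.2%, 26.8% and 44.8%).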

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

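The comparisons restricted to the 5 large arms or the 6 arms, without the X or above the X's 5th, 50th or 90th score percentile, those with replicate regions added to the region-free stretches, and the 5 kb width minimum were chosen after seeing the data. The excess of replicate overlap over chance remained under every alternative that had a null, with shares of replicate 1 regions between 63.7% and 73.6%. A requirement of 50% of both regions gave 49.4% and had no null. A minimum width of 1000 bp removed nothing and says nothing on stability. Keeping the higher-scoring 50% gave 6471 regions, by construction, over 30.3 Mb, of which 56.9% were in both replicates and 23.8% in neither. A 50% overlap gave 24.1% and 43.8%. Single replicate lists gave 7603 to 8137 regions over 22.4 to 23.9 Mb, and bases inside both lists gave 6452 segments over 15.6 Mb. Spearman's rho of scores was 0.67 for reciprocal pairs, 0.59 for pairs of one region with one region and 0.47 without the X. X coverage over the autosomal mean, 0.628 in the combined list, was 0.824 for the higher-scoring regions, 0.430 to 0.534 for single replicates, 0.362 for bases in both lists, 0.825 by number of regions, and 0.711, 0.860 and 0.745 above the X's 5th, 50th and 90th percentiles, all below 1. In the replicate 2 list it passed 1 above the 90th percentile (1.25). The fourth chromosome's ratio, 0.753 in the combined list, reversed to 1.11 for bases in both lists, spanned 0.831 to 1.14 over single replicates (1.14 in replicate 1), was 0.530 by number of regions, and 0.984 and 1.00 (just below 1) above the 50th and 90th percentiles. The cause of these changes was not tested. No paired analysis was possible because the inputs have no values of their own here. Alternatives for gene features, marked genes and gene lists were not run, for want of gene models of the same release. Unknown depth limits every comparison of list sizes.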

Other observations

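The region-free stretches, the counts of wide regions and the tests of a gradual threshold, of equal covered length, of regions in both lists and of higher-scoring regions, of other score percentiles, and of added length and of regions in a single replicate were chosen after the results were seen. Long stretches of the large arms held no H3K79me1 region. In the combined list 53 stretches of at least 100 kb made up 8.62 Mb, or 7.24% of the 5 large arms. Random placement of the same regions within each arm gave 0.01 such stretches on average and 1 at most over 100 draws (one-sided permutation p 0.0099, the smallest possible). Such placement leaves almost no gap of this length, so clustering of regions from any source would give this p. It shows only that the regions were not spread at random along the arms. The longest, 336 kb on 3R from 12478133 to 12814409, lay outside the centromeric bin of its arm, as did 248 kb on 2R from 2142241 to 2389969, 235 kb on 2L from 12455115 to 12689843 and 212 kb on 2L from 11284131 to 11496355. The longest assigned to a centromeric bin were 321 kb on 3L from 23337541 to 23658671 and 305 kb on 3R from 2584721 to 2889387. The 3R stretch runs on past the end of that bin, at 2790505. Of the 53, 18 were assigned to the centromeric bin of their arm, with this 3R stretch among them, and 35 to other bins. By arm, 18 lay on X, 13 on 2L, 8 each on 3L and 3R and 6 on 2R. In 34 of them neither replicate list had a base. Gaps of the assembly and sequence to which reads cannot be assigned were not analysed here and would look the same.

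The share of covered length in wide regions differed between the lists. In the combined list 590 regions of at least 10 kb (4.56% of regions) made up 10.1 Mb, or 23.6% of the covered length, and with a minimum of 5 kb the share was 45.9%. In the replicate lists the shares were lower, at 12.0% and 11.9% for 10 kb and 31.7% and 31.6% for 5 kb. In the combined list their median log2 score was 0.67, against 0.45 for narrower regions. There they numbered 6.66 per Mb on the fourth chromosome (9 regions), 6.43 per Mb on 2R, 5.27 on 3R, 5.05 on 3L, 4.22 on 2L and 2.36 on X. At this minimum the place of the fourth chromosome rests on few regions, as it held 2.22 per Mb (3 regions) in replicate 1 and 1.48 (2 regions) in replicate 2, against 1.89 and 2.41 on 2R. With a minimum of 5 kb it came first in all 3 lists, at 20.7 per Mb (28 regions) in replicate 1, 12.6 (17 regions) in replicate 2 and 25.9 (35 regions) in the combined list, against 8.80, 10.1 and 21.4 on 2R. The single region that the authors named as depleted lay on 3R from 4388308 to 4389686, with a log2 score of -0.0041.

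X regions covered less of the arm yet scored higher. The lower coverage is not accounted for by a hard score threshold alone. To test this, only regions scoring at least the X's 5th percentile were kept on all arms. The X then had at most 0.681 of the coverage of the lowest autosomal arm in the replicate lists, and 0.811 in the combined list. Whether a higher score was needed for a call on the X stays open, since the 5th percentile of the log2 scores of narrow regions exceeded that of every large autosomal arm by at least 0.0754 in the replicates, but the median did so by 0.10 and 0.16, so the whole distribution was shifted. A gradual threshold cannot be told apart from lower coverage, as above the X median the ratio to the lowest arm was 0.998 in replicate 1, 1.33 in replicate 2 and 1.09 in the combined list, and 1.05, 1.93 and 1.05 above the 90th percentile, so the X stayed below every autosomal arm only in replicate 1 above the median, but a limit taken from the X's own scores raises this ratio wherever the X scores higher. No biological explanation was tested, since the labels give no group by sex or X copy number.

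Replicate 1 covered more of the X, the fourth chromosome and the heterochromatic sequences, and less of the large autosomal arms, than replicate 2. As deposited, the ratio of X to autosomal coverage was 24.2% higher in replicate 1 (95% interval 17.6 to 30.9 from 1000 bootstrap draws of 1 Mb windows). The bootstrap intervals resample windows within 1 list per replicate, so they hold no variation between libraries. For these 2 lists, a different number of regions is argued against as the whole source, since at equal covered length the excess was 16.1% (10.2 to 22.3). Low-scoring regions near the threshold stay open. Over regions in both lists an excess of 9.87% (5.04 to 14.7) remained. That choice draws the lists together whatever the cause, so the fall from 24.2% cannot be credited to low-scoring regions. Nor does it remove them, since shared regions were not chosen by score. Over the higher-scoring 50% of each list an excess also remained, with a wide interval (11.4%, 4.04 to 19.2). A difference in depth or input between the replicates stays open, and no biological explanation was tested because the replicates belong to 1 group.

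The combined list covered more sequence than either replicate list, with 12.8 Mb outside both. Of this, 7.37 Mb (57.4%) lay in regions with no base in a replicate list, and 5.47 Mb (42.6%) extended regions found in at least 1 replicate, for which no explanation was tested. The smaller minimum width is argued against as the main source, since regions narrower than the narrowest replicate region made up 36.3% of the length of the regions in neither list and 20.9% of all added length. Weakness in single replicates stays open, because regions in neither list had a median log2 score of 0.42, below the 25th percentile (0.49) of regions in both, but regions called in 1 replicate scored almost the same (0.43), and between 1301 bp and 2 kb slightly lower (0.39 against 0.40). How the replicates were combined also stays open, and the design has no group that would give a biological explanation.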
